A study of Homo sapiens with 2 samples.

How the data were processed

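The data are RNA-seq values of 2 libraries from A549 cells, 1 labelled wild type and 1 labelled MYOCD knockdown. Per the labels, cells grew in DMEM with serum, total RNA was extracted with Trizol, and libraries were made with a TruSeq RNA kit and read on an Illumina HiSeq. The labels list doxycycline for 72 h for both samples, while the design text calls the wild type cells untreated, so whether those cells received doxycycline is not settled. The title of the knockdown sample is written as MYOCD-/-, the usual notation for a gene lost on both alleles, while its genotype label says knockdown. The sample is called a knockdown here after the genotype label, and how it was made is not given in the sources used here.

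The deposited values are RPKM (reads scaled by transcript length and by the mapped reads of the library), computed by the authors before deposit. TopHat2 2.0.10 and Cufflinks 2.2.1, and the builds GRCh38.p12 and BDGP5 (a fruit fly build), are named per the submitters' processing notes, which give no role for any of them. The annotation, the read filters and any use of strand are not given in the sources used here. Each line of the table is a locus with an RPKM per library. In loci that name several genes, which numbered 308, the value belongs to the locus. Loci with no gene name made up 1909 of 14952 (12.8%) and were left out of the comparison. The table also held 19 names changed into dates, which were matched to no gene. In every locus the higher of the libraries was at least 0.652 RPKM, so loci low in both are not in the values used here. RPKM need not sum to the same total, and the sums were 1.02e+06 in the wild type and 1.17e+06 in the knockdown library.

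No counts were given, so depth is unknown and no counting interval could be set. The low values were searched for steps of single reads: among 2212 loci under 2 RPKM in both libraries, at most 29 log2 ratios fell within any window of 0.01, and no relative depth could be read from them. A value of 0 is reported as listed at 0, with no fold.

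Values of the 102 names found on several lines were summed, which left 12936 named genes. Differences are log2((knockdown RPKM + 1) / (wild type RPKM + 1)), which understates the change of low genes. Genes with a mean of at least 1 RPKM (12158) were kept, and a size rule of 2-fold on this scale was used for counts. With 1 library per group there was no test, and no p-value or standard error is given. Current symbols and gene types came from a RefSeq gene table, which matched 94.0% of names. Coordinates, short RNA genes lying inside a locus on the same strand, GC content and transcript and UTR lengths came from GENCODE release 29 on GRCh38, and the authors' loci may have other boundaries. The short RNA genes looked for inside loci were microRNAs, small nucleolar RNAs and small Cajal body RNAs. A locus said to hold none may hold another kind.

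A list of genes was described by the percentile of its median log2 change among 10000 random lists of the same size, drawn from genes in the same of 20 bins of mean RPKM. Lists under the 2.5 or over the 97.5 percentile are called below or above, and lists with under 5 measured members were not compared. The 32 lists, the size rule, the alternatives other than those named in the next paragraph as added, and the rule for named genes were fixed before the data were examined. That rule takes MYOCD, SRF, MRTFA and MRTFB, the 12 highest and 12 lowest log2 changes among genes with a mean of at least 5 RPKM, and in each list the 2 highest and 2 lowest members. Some of the genes it takes are not reported here.

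Because the rule returned short RNA genes almost alone, protein-coding loci of 1 gene were also ranked, with and without those holding a short RNA gene, and further list members were named. These choices were made after the values were seen, as were 4 further gene lists (hypoxia, NF-kB, circadian clock and ERK output), the count with unnamed loci, the random lists matched on GC content and length or drawn from protein-coding genes, and the search of UTRs. In that search, the longest annotated 3′ UTR of each of 7817 protein-coding genes with a mean of at least 5 RPKM and no short RNA gene inside was scored for each 7-base word. The number of genes holding a word among genes at least 1.5-fold lower was set against the number expected from genes in the same of 20 bins of UTR length, and the largest excess was compared with those of 100 random gene sets of the same UTR lengths.

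The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data over 12158 genes, for the comparison of knockdown with wild type: 33% of genes changed by 2-fold and 95% of genes changed by 4-fold were recovered, 0 of 11958 unchanged genes were called, 4% of unchanged lists lay outside the central range, and 100% of lists shifted by 0.3 were found. All simulated genes had the same noise, independent between genes and small against the 2-fold rule. The 0 calls were thus built in and give no rate of false calls for these data. In protein-coding genes with no short RNA gene inside, the standard deviation of the log2 changes was 0.336 at a mean of 1 to 2 RPKM. It was 0.191 at 200 RPKM and above. Alternatives covered the pseudocount (0.1 and 5), the filter (none and a mean of 5 RPKM), the scaling (median of ratios, upper quartile, equal sums, trimmed mean of log ratios), the size rule (1.5-fold and 3-fold) and the mean of a list in place of its median.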

Results

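RNA-seq was used to compare A549 cells, an established human lung adenocarcinoma line, with A549 cells in which MYOCD was knocked down. MYOCD encodes myocardin, a coactivator that binds serum response factor and drives smooth and cardiac muscle genes. Each group had 1 library, so no value has a replicate error and no difference was tested. The labels leave open whether the wild type cells received doxycycline as the knockdown cells did, and if they did not, each difference between the libraries is also one between treated and untreated cells. The question, as the series describes it, was how the transcriptome differs between the wild type and knockdown cells. The deposited values are RPKM, with no read counts, so the depth of each library is unknown. They covered 14952 loci, with medians of 9.06 RPKM in the wild type library and 8.94 in the knockdown library. Where a pair of RPKM values is given for a gene, the wild type library comes first.

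The targeted gene was near the floor of the measurement. MYOCD, listed by its symbol and annotated on the plus strand of chromosome 17 from 12665890 to 12768949 (GENCODE release 29, GRCh38), had 0.881 RPKM in the wild type library and 0.400 in the knockdown library. The labels call this sample both a knockdown and MYOCD-/-, a notation for loss of both alleles. The knockdown level was 45.5% of the wild type level, a log2 ratio of -1.14, or -0.43 with a pseudocount of 1. Among 581 other protein-coding loci with a mean of 0.5 to 1 RPKM, 76 (13.1%) differed by at least as much in either direction. Loci under 0.652 RPKM in both libraries are absent, so those with the lowest means are present only if the libraries differ. This raises the share. The partners and relatives of myocardin differed little. SRF, the DNA-binding partner, had 9.23 and 8.82 RPKM, MKL1 (now MRTFA) had 13.1 and 12.5, and MKL2 (now MRTFB) had 10.8 and 10.7.

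In the knockdown library, fixed lists of genes induced by hypoxia, NF-kB targets with chemokines, and ATF4 targets of the integrated stress response were lower as groups. Those of heat shock and p53 target genes were higher. A further list of NF-kB targets, made after the values were seen, was not lower than random lists (percentile 24.96). The lowest single messages included CCL20, a chemokine of the NF-kB response, and ANGPTL4, a secreted inhibitor of lipoprotein lipase. ODZ2 (now TENM2), a teneurin adhesion protein, and NPTX1, a neuronal pentraxin, were among the higher ones. Of 20 listed smooth muscle genes that myocardin is known to drive, 11 were measured, and these did not stand apart as a group. Most genes had similar levels in both libraries: of 12158 named genes with a mean of at least 1 RPKM, 79 were at least 2-fold higher and 88 at least 2-fold lower in the knockdown library. Across these genes, which are not independent replicates, Pearson's r between the log2 values was 0.941 and Spearman's rho was 0.959. Rescaling each library to the same summed RPKM lowered all log2 changes by about 0.20 before the pseudocount and gave 68 higher and 140 lower genes. The sums differ almost wholly in loci with no gene name, which held 42.3% of the wild type sum and 49.5% of the knockdown sum. This factor thus comes from loci that the comparison left out.

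Short RNA genes held the most extreme values. Among 162 genes for small nucleolar RNAs, microRNAs and other short RNAs, 54 were 2-fold higher, 42 were 2-fold lower, and 74 were listed at 0 in 1 library. Of the 24 genes with the most extreme log2 changes at a mean of at least 5 RPKM, 23 were of this kind and were listed at 0 in 1 library. SNORD79 and MIR647 were listed at 5626 and 565 RPKM in the wild type library and at 0 in the knockdown library. MIR4492 and MIR1908, both at 3614 RPKM, and SNORD35A, at 1311 RPKM, were listed at 0 in the wild type library. In transcripts this short few reads give a large RPKM, and no counts were given, so such pairs need not be large differences in reads. The remaining gene was MXD4, which encodes a MAX-binding repressor, with 11.8 and 6263 RPKM. MXD4 holds a short RNA gene on its own strand, as do CPSF1 (2024 and 27.3 RPKM), DGCR8, TMEM42 and PHC2, so these values cannot be read as levels of the messages alone.

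Protein-coding loci of 1 gene with no short RNA gene inside showed far fewer large differences. Of 10153 such genes, 11 were 2-fold higher and 38 were 2-fold lower, and the central 95% of their log2 changes ran from -0.61 to 0.47. The genes named from this group, chosen after their values were seen, had a mean of at least 5 RPKM. The lowest were CCL20 (14.6 and 3.30 RPKM) and ANGPTL4 (38.6 and 10.5 RPKM), with log2 changes of -1.86 and -1.79. HPD, an enzyme of tyrosine breakdown, had 9.68 and 2.96 RPKM, and the calcium-binding proteins S100A9 and S100P had 20.6 and 7.48 RPKM and 22.2 and 9.31 RPKM. KCTD9 had a log2 change of -1.33, and IGFBP3, which binds insulin-like growth factors, had 130 and 64.2 RPKM. CALM2, a gene for calmodulin, had 825 and 363 RPKM, while CALM3, another calmodulin gene, had 246 and 347 RPKM. TMEM64, SGPP1, SLC50A1 and KREMEN1 were also lower, by log2 changes of -1.32, -1.30, -1.25 and -1.15. Of the 23 such genes that were at least 2-fold lower, had an annotated 3′ UTR and had a mean of at least 5 RPKM, 10 carry the bases AATATGC in that UTR, among them CALM2, IGFBP3, TMEM64, SGPP1, SLC50A1 and KREMEN1. This word was picked as the most enriched one in genes at least 1.5-fold lower, these included.

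**Figure D1:**
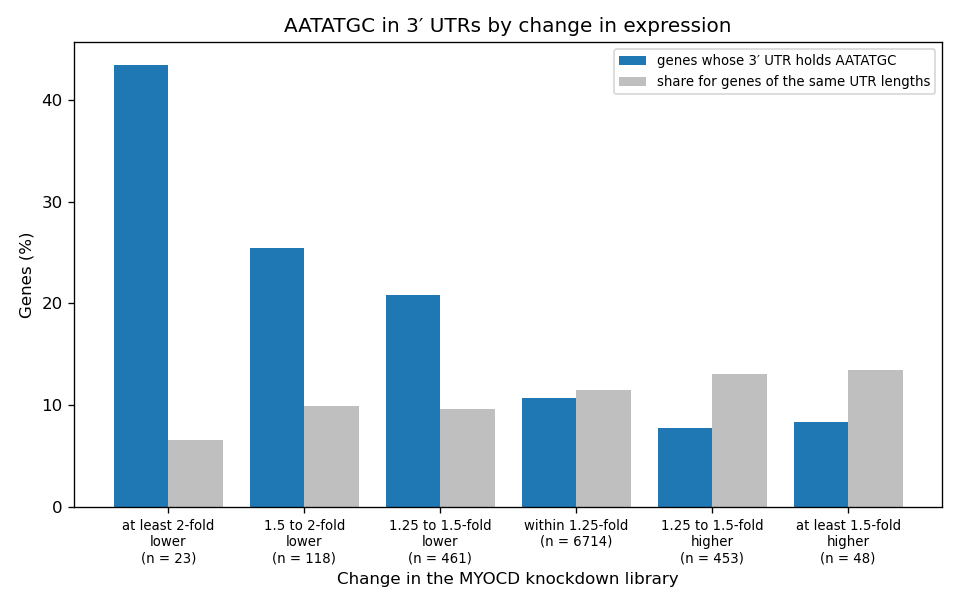
Share of genes (vertical axis, %) whose 3′ UTR holds AATATGC, in classes of fold change in the MYOCD knockdown library (horizontal axis), for 7817 protein-coding genes; grey bars give the share expected from genes of the same UTR lengths. The word was picked in the 2 leftmost classes, whose shares the pick raises; in the 461 genes of the next class, left out of the pick, the share was 20.8% against 9.64% expected, and in the 48 genes at least 1.5-fold higher it was 8.33% against 13.4%.

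The highest of these genes was ODZ2, with 8.83 and 43.9 RPKM and a log2 change of 2.19. DNAH10, a dynein heavy chain, had 3.26 and 9.08 RPKM, NPTX1 had 27.1 and 62.6 RPKM, and the pseudokinase PEAK1 had 8.29 and 19.5 RPKM. The chromatin protein HMGA2 had 14.0 and 27.8 RPKM, and NT5E, the ecto-enzyme CD73, had 4.30 and 9.21 RPKM.

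**Figure D2:**
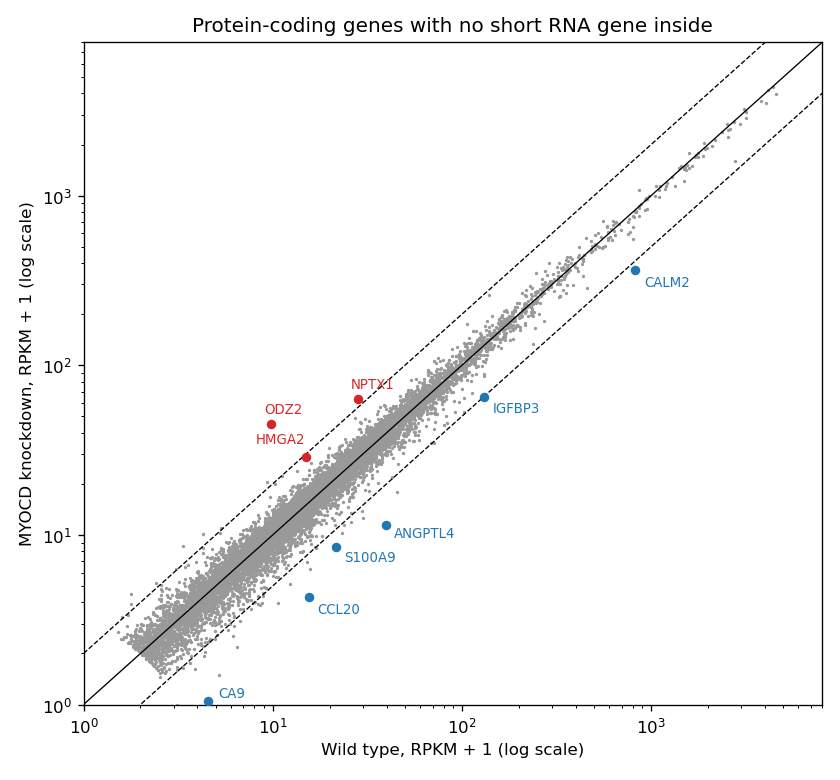
Expression in the MYOCD knockdown library (vertical axis) against the wild type library (horizontal axis), as RPKM + 1 on log scales. Each point is 1 of 10153 protein-coding genes with no short RNA gene inside, the solid line marks equal values and the dashed lines a 2-fold difference; ODZ2 lies above the upper dashed line, and CCL20, ANGPTL4, CALM2 and CA9 lie below the lower one.

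Of 32 gene lists fixed before the data were examined, 28 had enough measured members to be compared with 10000 random lists of the same size and mean expression, as a description of these libraries. The medians of 2 lists lay above the central 95% of their random lists and those of 7 lay below. For lists of genes drawn at random, 0.7 would be expected on each side. Members of a list can vary together between any 2 cultures, so more lists could lie outside with no effect of the knockdown. How many was not estimated. When the mean replaced the median, 0 lists lay above and 3 below (NF-kB, hypoxia and histone genes). In that setting the random lists also drew the short RNA genes with extreme values. When the lists and random lists were limited to protein-coding genes with no short RNA gene inside, a setting chosen after the data were seen, the mean gave 5 lists above and 5 below.

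Hypoxia-induced and glycolysis genes were lower, with a median log2 change of -0.34 over 22 genes (percentile 0), and 21 of the 22 were below 0. The lowest were CA9, the hypoxia-induced carbonic anhydrase (3.57 and 0.043 RPKM), and ALDOC, a glycolytic aldolase (4.17 and 0.492 RPKM). NDRG1 had 67.2 and 33.9 RPKM, the glucose transporters SLC2A3 and SLC2A1 had log2 changes of -0.64 and -0.50, and the oxygen sensor EGLN3 had 9.50 and 6.18 RPKM. The glycolytic enzymes LDHA (823 and 804 RPKM) and PFKP (297 and 308 RPKM) differed least. The list stayed below its random lists in 12 of 12 alternative settings, with medians from -0.51 (equal sums) to -0.27 (a mean of at least 5 RPKM). The scalings among these settings move a list and its random lists nearly alike, so they could hardly change the outcome.

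NF-kB target and cytokine genes had a median log2 change of -0.36 over 17 genes (percentile 0), and 14 were lower. Besides CCL20, the prostaglandin synthase PTGS2 had 42.0 and 20.8 RPKM, and the chemokines CXCL1 and IL8 (now CXCL8) had 31.3 and 17.2 RPKM and 28.6 and 19.4 RPKM. BIRC3, an inhibitor of apoptosis and also an NF-kB target, was higher at 19.0 and 23.2 RPKM, and NFKB2 had 36.9 and 37.4 RPKM. This list too stayed below in 12 of 12 alternative settings, of which the scalings could again hardly change the outcome. Its medians ran from -0.53 (equal sums) to -0.22 (a mean of at least 5 RPKM). The bases AATATGC occur in the 3′ UTRs of PTGS2, ICAM1 and TNFAIP3, and without those 3 members the median was -0.21. A further list of 11 NF-kB targets, made after the values were seen, had a median of -0.04 (percentile 24.96) and did not extend the pattern.

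ATF4 targets of the integrated stress response had a median log2 change of -0.25 over 20 genes (percentile 0), with 14 lower. DDIT3, the stress factor CHOP, had 10.2 and 6.37 RPKM, the mTORC1 inhibitor DDIT4 had 270 and 182 RPKM, and ATF4 itself had 202 and 167 RPKM. The amino acid transporter SLC7A5 went the other way, with 391 and 592 RPKM. Its median ranged from -0.43 with equal sums to -0.17 with a pseudocount of 5. With the mean in place of the median this list lay at percentile 10.6, and at 0.14 when limited to protein-coding genes with no short RNA gene inside.

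Replication-dependent histone genes, whose messages mostly lack a poly(A) tail, had a median of -0.29 over 10 genes (percentile 0.24). Of these, 7 were lower and 3 higher. HIST1H4H, which carries AATATGC in its 3′ UTR, had 7.33 and 2.89 RPKM, and HIST1H4A was listed at 2.14 RPKM and at 0. HIST1H2AC had 14.2 and 15.8 RPKM and HIST1H4C had 1.11 and 1.55 RPKM. HIST1H4I, another H4 gene outside the list, was higher at 0.780 and 2.91 RPKM. Histone genes share near-identical sequence, so reads may be split among them, and the list lay inside its random range at percentile 6.87, with a median of -0.14, when a mean of at least 5 RPKM was required. With equal sums its median was -0.46.

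The other 3 lists below their random lists had small shifts or few members. NRF2 targets, which A549 cells express at high levels, had a median of -0.06 over 24 genes (percentile 1.66) and a mean of 0.0079, which has the opposite sign. Limited to protein-coding genes with no short RNA gene inside, the mean was -0.02 (percentile 19.9), so the call was lost with either mean. HMOX1, which degrades heme, had 81.4 and 62.7 RPKM, and SRXN1, which repairs oxidised peroxiredoxins, had 144 and 194 RPKM. G2/M genes had a median of -0.06 over 22 genes (percentile 2.18), with the mitotic kinase AURKA at 69.8 and 40.9 RPKM and CCNB1 at 122 and 126 RPKM, and lay below in 7 of 12 alternative settings. With equal sums the NRF2 and G2/M medians were both -0.26, at percentiles 1.97 and 2.75. Alveolar and airway genes had a median of -0.30 over 6 genes (percentile 1.95), with NAPSA at 1.27 and 0.771 RPKM. They lay below in 4 of the 8 alternative settings that left enough members. Those 4 were no filter and scalings, which could hardly change the outcome. At pseudocounts of 0.1 and 5 the percentiles were 3.24 and 4.92, with a median of -0.12 at 5.

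Heat shock genes were higher, with a median log2 change of 0.33 over 14 genes (percentile 100), and 11 of the 14 were above 0. HSPA4L had 13.1 and 18.7 RPKM, HSPH1 had 65.5 and 87.1 RPKM, and HSPA1A, which shares nearly all of its sequence with HSPA1B and is uncertain for that reason, had 30.7 and 42.7 RPKM. HSP90AB1, the constitutive HSP90 gene, was lower at 798 and 553 RPKM. p53 target genes had a median of 0.23 over 22 genes (percentile 99.98), with 17 higher. The death receptor FAS had 7.37 and 11.1 RPKM, the antiproliferative gene BTG2 had 12.3 and 18.1 RPKM, and the p53 inhibitor MDM2 had a log2 change of 0.43. The stress cytokine GDF15 was lower at 211 and 111 RPKM. With the mean in place of the median the heat shock and p53 lists lay at percentiles 82.2 and 88.1. Limited to protein-coding genes with no short RNA gene inside, the means lay at 99.87 and 100. With the libraries rescaled to equal sums the medians were 0.13 and 0.05, still above the random lists.

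**Figure D3:**
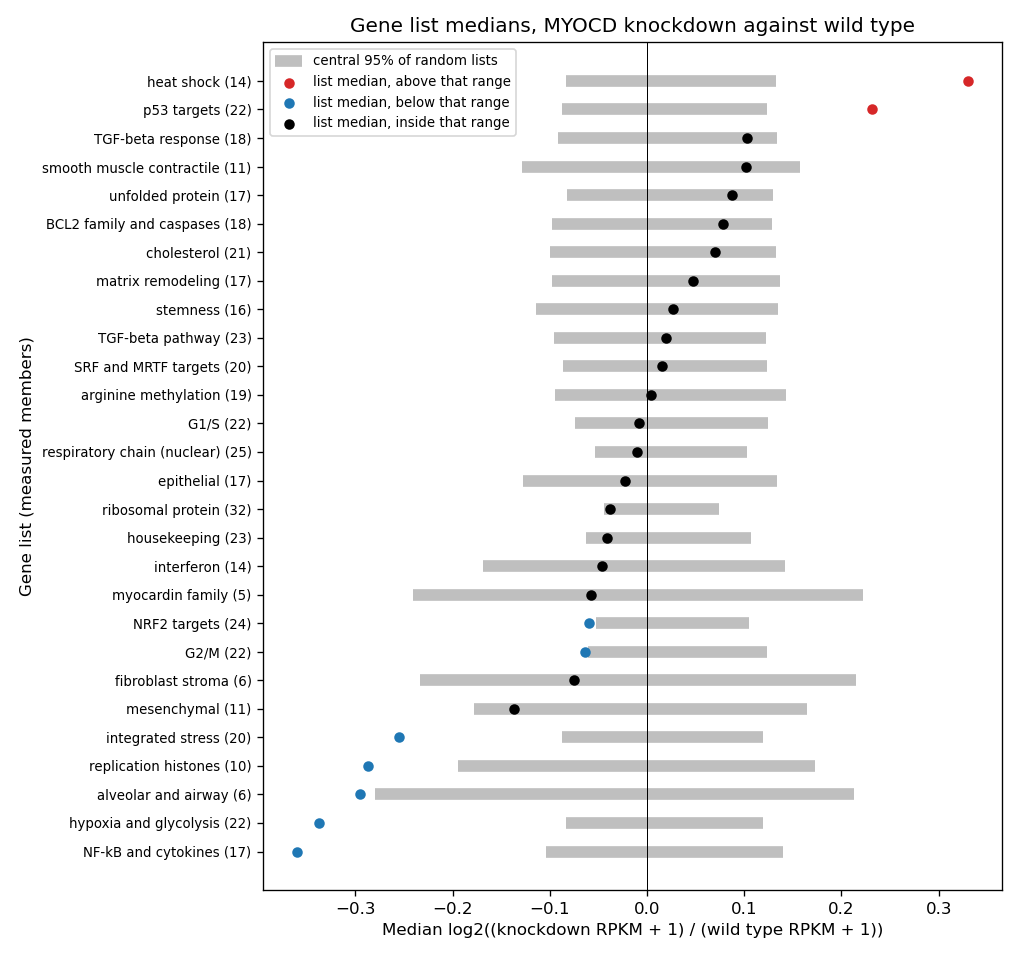
Median log2((knockdown RPKM + 1) / (wild type RPKM + 1)) of each of the 28 compared gene lists (horizontal axis), with the number of measured members in brackets and the central 95% of 10000 matched random lists as a grey bar. Red points (heat shock, p53 targets) lie above that range and blue points lie below it, with the NF-kB list lowest at -0.36.

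The muscle lists did not stand apart. Smooth muscle contractile genes had a median of 0.10 over 11 genes (percentile 88.9), with TPM1 at 118 and 159 RPKM, ACTA2, smooth muscle actin, at 12.4 and 16.9 RPKM, and TPM2 at 174 and 164 RPKM. The list held 20 genes, and MYH11, CNN1, ACTG2 and LMOD1 were among those not measured. TAGLN was measured only in a locus shared with SIDT2. The result thus does not cover these myocardin targets. Cytoskeletal and early genes with serum response factor sites had a median of 0.02 over 20 genes (percentile 49.2), with the matrix protein THBS1 at 6.70 and 10.3 RPKM and the early gene EGR1 at 4.15 and 2.52 RPKM. The myocardin family list had a median of -0.06 over 5 genes (percentile 29.2). Of the cardiac list, 4 genes were measured, too few to compare, with GATA4 at 1.36 and 1.70 RPKM and TNNI3 at 4.01 and 2.97 RPKM.

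TGF-beta ligands, receptors and SMADs lay in the middle of their random lists, at percentile 52.0 over 23 genes, with the receptor TGFBR2 at 42.1 and 55.7 RPKM. Genes induced by TGF-beta had a median of 0.10 over 18 genes (percentile 93.0), with PMEPA1 (18.7 and 31.7 RPKM) near the upper end and the helix-loop-helix gene ID1 (383 and 296 RPKM) at the lower. Mesenchymal genes had a median of -0.14 over 11 genes (percentile 5.99). CDH2, N-cadherin, had 1.72 and 3.84 RPKM, while FN1, fibronectin, had 71.2 and 51.2 RPKM. Epithelial genes lay at percentile 32.1, with the junction protein JUP at 78.6 and 53.9 RPKM and occludin, OCLN, at 4.90 and 5.22 RPKM. Markers of stem-like cancer cells lay at percentile 58.7, with LIN28B, which binds let-7 precursors, at 1.57 and 3.77 RPKM and NOTCH3 at 21.7 and 14.7 RPKM.

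The remaining lists also lay inside their random ranges. G1/S genes lay at percentile 24.0, interferon-stimulated genes at 29.4, endoplasmic reticulum chaperones at 89.0, cholesterol synthesis genes at 80 and nuclear genes of the respiratory chain at 21.1. Cytosolic ribosomal protein genes lay at 4.64, matrix and protease genes at 68.0, BCL2 family and caspase genes at 85.0, and arginine methylation and chromatin genes at 36.2. HDAC5, a histone deacetylase in the last of these, had 4.82 and 2.40 RPKM. Fibroblast genes lay at percentile 24.1, and the endothelial and leukocyte lists had 1 and 2 measured genes. No gene of the mitochondrial genome was among the values used here. Reference genes used for normalization had a median log2 change of -0.04 over 23 genes (percentile 7.41), with single genes from -0.40 for GPI to 0.18 for HPRT1.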

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

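The test of short RNA genes inside loci was chosen after the result was seen.

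Loci with no gene name, which the comparison left out, held 42.3% of the summed RPKM in the wild type library and 49.5% in the knockdown library. Of 1809 such loci with a mean of at least 1 RPKM, 126 were 2-fold higher and 176 were 2-fold lower in the knockdown library. Their identity was not analysed here.

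Among 7 protein-coding loci of 1 gene with an absolute log2 change of 2 or more, 5 (71.4%) hold a microRNA or small nucleolar RNA gene on the same strand: CPSF1, MXD4, DGCR8, TMEM42 and PHC2. The share was 7.72% among all 11006 such loci and 9.43% among the 53 with an absolute log2 change of 1 to 2. A candidate explanation is that the RPKM of these loci took in the value of a very short transcript, for which few reads give a large RPKM. The other members of the group, CA9 and ODZ2, hold none. No biological explanation was tested for the 5 loci, and a real difference in the short RNAs stays open.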

How the results depend on the processing

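Settings that single out protein-coding loci, add unnamed loci or draw random lists from protein-coding genes were chosen after the data were seen. No paired analysis was possible because each group has 1 library. The main counts were 79 higher and 88 lower genes. The lower count was 189 with a pseudocount of 0.1, 53 with 5, 140 with equal sums, 389 at 1.5-fold and 45 at 3-fold, and the higher count was 201 at 1.5-fold. Protein-coding loci of 1 gene gave 17 higher and 43 lower, those with no short RNA gene inside gave 11 and 38, and adding unnamed loci gave 205 and 264. The correlation of 0.941 became 0.905 and 0.954 with pseudocounts of 0.1 and 5, 0.904 at a mean of at least 5 RPKM, and 0.986 over protein-coding loci. The log2 change of MYOCD was -0.97 and -0.12 with pseudocounts of 0.1 and 5. A mean of at least 5 RPKM left 4 lists below. The mean of each list gave 0 lists above and 3 below and turned the NRF2 value to 0.0079. Limited to protein-coding loci with no short RNA gene inside, the mean of the NRF2 list was -0.02, and the means gave 5 lists above, adding stemness, matrix and BCL2 family genes to heat shock and p53 targets. Apart from equal sums and the settings whose construction changes which genes are counted or how far a log2 value can reach, the cause was not tested. Equal sums moved the median of all genes to -0.17, because the sums differ almost wholly in loci with no gene name. The other scalings moved it to within 0.01 of 0. Of 516 values of 86 named genes under alternatives, 487 kept their direction and side of the 2-fold rule. Of 371 values of 31 lists, 330 kept theirs. Scalings other than equal sums shift log2 values by only -0.011 to -0.015, so the values under them could hardly change and these counts overstate stability. Among the named genes 0 called ones changed sign, but this was fixed in advance. A pseudocount keeps the sign, and the largest scaling shift, -0.20, is too small to reverse a 2-fold change. In the UTR search AATATGC was also the top word at a mean of at least 10 RPKM; with a 2-fold rule and at a mean of at least 20 RPKM the top words were TATATTT and CTCCTTG, and AATATGC was not ranked because under 5 genes were expected to hold it. These settings were chosen after the data were seen and use parts of the same lower genes. Depth is unknown, so its effect on low genes such as MYOCD could not be measured.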

Other observations

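The tests of scaling and of the 7-base word in separate parts of the genes were chosen after the results they bear on were seen, and the search of UTRs after the excess of lower genes was seen.

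Beyond the fixed lists, 4 further lists were made after the values were seen. Of 19 further hypoxia genes 15 were lower, with a median log2 change of -0.12 at percentile 0.905 of random lists; the secreted hormone STC1 had 9.04 and 4.70 RPKM and MXI1, a MYC antagonist, had 12.4 and 8.05 RPKM. The other 3 lists lay inside their random ranges. Further NF-kB targets had a median of -0.04 over 11 genes (percentile 24.96), with CCL5 at 6.28 and 3.08 RPKM and NFKB1 at 10.1 and 13.4 RPKM. Circadian clock genes had a median of -0.16 over 10 genes (percentile 8.72), with PER1 at 6.61 and 3.82 RPKM. They were looked at because DBP was lower, at 14.1 and 5.95 RPKM, and ARNTL2 higher. DBP is not among the 10. ERK output genes, looked at because HMGA2 was among the higher genes, had a median of -0.08 over 13 genes (percentile 8.04). GPRC5A, a retinoic acid-induced receptor, had 248 and 824 RPKM, and its locus holds MIR614.

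MYOCD had a lower value in the knockdown library, but 13.1% of protein-coding loci at a mean of 0.5 to 1 RPKM differed as much. That share is raised by the absence of loci under 0.652 RPKM in both libraries, so it does not measure scatter fairly. Scatter at low expression stays open as an explanation.

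The hypoxia and NF-kB lists were both lower in the knockdown library. GC content and transcript length are argued against, since with random lists matched on them as well the higher of the percentiles was 0. Scaling is argued against too, since 1 factor for every gene would move all genes alike. The medians of these lists differed from that of all genes by -0.35 (hypoxia) and -0.37 (NF-kB). AATATGC lies in the 3′ UTR of 1 hypoxia member of 21 with a UTR, so leaving it out could hardly move that list. Without its 3 holders the NF-kB median moved from -0.36 to -0.21, still at percentile 0. Matches to this exact word in the members' own UTRs are thus argued against as the whole explanation. Members holding the overlapping word ATATGCA were not left out, so matches to related words were not tested. An effect through other genes that hold the word was not tested. A difference between the cultures at harvest, such as density or oxygen, cannot be told apart from the knockdown, because there was 1 library per group, and neither can doxycycline itself if the wild type cells had none. The knockdown itself stays open as a hypothesis, and the further NF-kB targets, at percentile 24.96, did not extend the NF-kB pattern.

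More protein-coding genes were lower than higher, and a part of the lower ones held the same word in their 3′ UTRs. The lower genes without this exact word still outnumbered all of the higher ones, so its holders do not make up the whole excess. In the 461 genes left out of the pick, described below, the next most enriched word was ATATGCA, which overlaps it. Holders of ATATGCA were not set aside, so how far related matches account for the excess was not tested. AATATGC occurred in the UTR of 40 of 141 genes at least 1.5-fold lower, against 13.2 expected, and 0 of 100 random gene sets had a word as enriched, while for the 48 genes at least 1.5-fold higher 33 of 100 did. Chance is argued against by 461 genes left out of the pick, with log2 changes between -0.58 and -0.32, where 96 held the word against 44.4 expected (percentile 99.99 of all words), and base composition by other words of the same bases, held there by a median of 0.899 times the expected number of genes against 2.16 times for AATATGC; picking in each part of a random split was mixed, with AATATGC at percentile 99.98 in the other part and a different word, GCGGGGC, at 77.9. These values are consistent with the hypothesis that a small RNA used for the knockdown lowered messages with matches to its seed, such as CALM2, IGFBP3 and PTGS2, though how the knockdown was made is not given in the sources used here and the sample's title, MYOCD-/-, is a notation for a null genotype. The word occurs in 2 of 3 coding MYOCD transcripts, in the coding sequence at 12717403 to 12717409 on chromosome 17 (GENCODE release 29, GRCh38), as a guide fully matched to MYOCD would need, but 39.6% of transcripts of similar length hold it too.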
